A study of Homo sapiens with 16 samples.

How the data were processed

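The series holds 16 libraries of H9 human embryonic stem cells, 8 of total RNA and 8 of RNA bound to ribosome-nascent chain complexes (RNC). They form 8 pairs of an RNA and an RNC library with the same label, each pair called a culture here. The labels do not say whether the 2 cultures of a group were grown separately. Cells received a control siRNA or an siRNA against OCT4 and were kept at 20% or 1% oxygen, with 2 cultures in each of the 4 groups. The deposited table gives, for 28252 genes, 1 value per culture in the unit ratio, the translation ratio that the authors computed as the RNC value over the RNA value. Its columns marked "sO" were read as the siOCT4 cultures. Per the submitters' processing notes, edgeR and the genome build hg19 were used; their role, the mapper, the annotation, filters and the library totals behind the ratio are not given in the sources used here. No counts or levels of single libraries are in the table, so the planned comparisons of RNA levels and of RNC levels, a minimum level of expression and matching on RNA level could not be made, and the depth per library is not given. Because of this, a change of the ratio can come from the RNC level or the RNA level.

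A ratio was given in all 8 cultures for 15864 genes, in some for 4505 and in none for 7883; the genes with a ratio in all 8 were tested. Ratios that at least 3 genes of a culture shared within a relative tolerance of 2e-06 were called recurrent, since such values come from small read numbers; 8087 tested genes had no recurrent ratio. GC content, length and type of transcripts came from GENCODE release 29, which is on another genome build and was used for no coordinates. It was matched by symbol for 25761 genes, and 15261 tested genes (96.2%) had a GC content.

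The log2 ratio was fitted with limma 3.58.1 (statmod 1.5.0, R 4.3.3), with trend and robust settings, 4 group means and 4 residual degrees of freedom. The 5 comparisons were siOCT4 against control siRNA at 20% and at 1% oxygen, 1% against 20% oxygen in control and in siOCT4 cells, and the interaction of both factors. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes of a comparison and a threshold of 0.05. The p-values measure the spread between these samples, since the labels do not say whether the replicates were grown separately. The 30 gene lists were tested with camera (preset correlation 0.01), adjusted over the lists of a comparison, with camera at an estimated correlation and fry beside it; fry asks whether the genes of a list move one way and compares it with no other genes. A list needed 5 measured members, and 29 lists had them; none of the 13 mitochondrially encoded mRNAs was in the table (0 measured). Within control cells at 20% oxygen the median log2 ratio of each list was placed among 10000 random lists of the same size, as a description. Profiles and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

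The comparisons, tests, gene lists and the rule for naming genes were fixed before the data were examined. The rule took POU5F1, the 10 genes per direction with the largest change among those past the threshold with both cultures of a group apart from both of the other, and up to 4 members of each list by size of change (2 where none passed). Of the 20 genes ranked by size of change, 18, 16, 14 and 20 in the first 4 comparisons and 16 in the interaction had a recurrent ratio. The genes described are a subset of those the rule named, chosen after their values were seen, which leaves out most genes with a recurrent ratio or with calls that changed with the GC correction; how many of the described genes pass is therefore not a measure of how many calls hold.

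The GC correction replaced each log2 ratio by its residual from a spline (6 degrees of freedom) of the culture's log2 ratios on transcript GC content. It, a correction for GC content and length, quantile normalization, and leaving out genes with a recurrent ratio were added after the data were seen. Alternatives fixed beforehand were median centring, the replicate number as a block, limma without trend and robust settings, pseudocounts of 0.01 and 0.1, a fit of only the groups compared, and leaving out each culture in turn. With 1 culture left out, the lone culture of a group was assumed to vary like those of the other groups.

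The fit was tested on simulated data with the spread of these cultures. Of 100 genes given a log2 change of 1, limma called 5, 12, 12 and 10 in the first 4 comparisons and 0 in the interaction, and of 100 given a change of 2 it called 66, 71, 73, 69 and 0. Among the unchanged genes of the 15864 simulated it called 4, 6, 11, 5 and 0. Only these seeded genes changed in the simulation, whereas 8450 to 10893 genes passed in the real fits. The adjusted threshold was therefore stricter in the simulation, and these rates do not measure how small a change the real fits could call. A linear GC trend was then added, with the same slope in each control culture at 20% and siOCT4 culture at 1% oxygen and none elsewhere. With it, limma called 9308, 9367, 9377, 9382 and 11183 unchanged genes of the 15261 simulated, and 3, 4, 12, 5 and 0 after the GC correction. The correction removes such a trend by construction. In the real cultures slopes differed within groups (-1.524 and -1.143 per 10 percent in control cells at 20%). The correction is fitted to each culture, so unlike slopes do not prevent it. Its success in the real cultures was not tested.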

Results

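H9 human embryonic stem cells received a control siRNA or an siRNA against OCT4 (POU5F1) and were kept at 20% or 1% oxygen. The translation ratio of a gene, its level in RNA bound to ribosome-nascent chain complexes over its level in total RNA, was compared across 8 cultures, 2 in each of the 4 groups, for 15864 genes with a ratio in every culture. Changes are given as folds or as log2 differences ± SE with limma's adjusted p over all genes tested. The n is 2 cultures per group throughout, where a culture is a labelled replicate that may not have been grown separately.

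In 2 of the 4 groups the ratio depended on the base composition of the transcript. Genes of any type with a transcript GC content under 42% (3122 genes) had median ratios of 4.85 and 4.06 in the 2 control cultures at 20% oxygen. Those over 58% (3622 genes) had median ratios of 0.415 and 0.638. In siOCT4 cells at 1% oxygen the medians were 3.77 and 3.80 for the AT-rich genes and 0.489 and 0.476 for the GC-rich genes. In control cells at 1% oxygen they were 1.01 and 1.23 against 1.04 and 0.808, and in siOCT4 cells at 20% oxygen 1.37 and 1.32 against 0.978 and 1.02. GC content accounted for 63.8% to 71.0% of the variance of the log2 ratio across genes in the first 2 groups named and for 0.0757% to 14.1% in the other 2, with genes not being independent replicates. Among 608 lincRNAs and antisense RNAs, which code for no long protein, the log2 ratio also fell with GC content, by 1.09 and 0.76 per 10 percent in control cells at 20% oxygen and by 0.81 and 0.90 in siOCT4 cells at 1% oxygen. Each of the first 4 comparisons therefore set a group with a steep trend against a group with a flat one. For this reason counts of genes and some of the list tests are also given on values relative to the GC trend of each culture ("GC corrected", 15261 genes), a choice made after the data were seen. In the 5 comparisons 4, 12, 9, 4 and 9 lists passed camera at the preset correlation as deposited. GC corrected, 5, 17, 10, 9 and 14 passed, and 3, 11, 6, 4 and 7 passed in both. Folds and log2 values of single genes are of the ratios as deposited. Where the correction changed a fold by more than 1.5 times, the corrected value follows it, marked "corrected". Transcript length also went with the ratio, and the GC correction does not model it. Across mRNAs the Spearman correlation with length was 0.381 and 0.373 in siOCT4 cells at 1% oxygen and 0.152 and 0.127 in control cells at 20%. It was -0.157 and -0.259 in siOCT4 cells at 20% and -0.226 and -0.000112 in control cells at 1%.

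**Figure D1:**
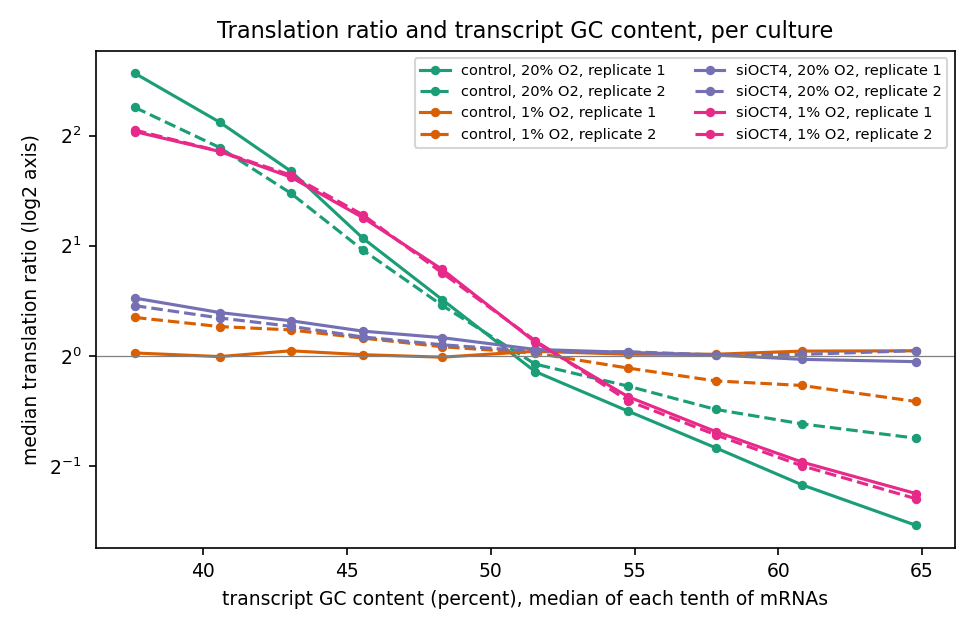
Median translation ratio (log2 axis) of mRNAs in 10 bins of transcript GC content (percent), one line per culture, coloured by group, with replicate 2 dashed. Control cultures at 20% oxygen fell from medians of 5.92 and 4.77 in the lowest bin to 0.344 and 0.596 in the highest, and siOCT4 cultures at 1% oxygen from 4.10 and 4.14 to 0.420 and 0.407, whereas the other 4 cultures stayed between 0.750 and 1.44 in these bins.

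Within control cells at 20% oxygen, mRNAs of glycolysis, the pathway that turns glucose into pyruvate, were among those with the lowest ratios. Their median ratio was 0.422 (21 genes), below all 10000 random lists of the same size. Targets of ATF4, the transcription factor of the integrated stress response, had a median of 0.433 (30 genes), and collagens and other matrix mRNAs a median of 0.435 (37 genes), both also below all random lists. Fibroblast and stroma markers (0.419, 11 genes, percentile 0.03) and trophectoderm and trophoblast markers (0.615, 16 genes, percentile 0.94, but 5.43 GC corrected and 3.68 without replicate 2) were the other lists under the 2.5 percentile, and the remaining 24 lists lay between this percentile and its counterpart at the upper end. Cytosolic ribosomal protein mRNAs had a median ratio of 0.891 (percentile 4.08, and 0 GC corrected) and nuclear-encoded respiratory chain mRNAs one of 1.34. These percentiles describe the culture means and carry no p-value; 10 lists lay under the 2.5 percentile without replicate 1 and 4 without replicate 2. GC corrected, 12 lists lay below and 1 above, the mitochondrial ribosomal proteins at percentile 99.6. Besides the cytosolic ribosomal proteins, those newly below were naive pluripotency, endoderm, HIF-responsive genes, translation factors, cell cycle, tRNA synthetases and non-coding RNAs. The mitochondrial ribosomal proteins were at percentile 79.4 as deposited and 77.0 with GC content and length corrected, where 14 lists lay below and 0 above.

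At 20% oxygen, mRNAs of stress-induced genes had higher ratios in siOCT4 than in control siRNA cells, although 0 lists passed with an estimated correlation (lowest adjusted p = 0.539, and 0.423 GC corrected). GDF15, a secreted cytokine of the cellular stress response, rose 54.9-fold (27.5 corrected; 5.78 ± 0.31 on the log2 scale, adjusted p = 0.000653), and DDIT3, the stress-induced transcription factor CHOP, rose 5.89-fold (2.56 ± 0.15, adjusted p = 0.000653). The ratios of LIN28B, an RNA-binding protein of pluripotent cells, and CDK1, the kinase that drives entry into mitosis, fell 5.49-fold (2.27 corrected; -2.46 ± 0.20) and 5.83-fold (1.64 corrected; -2.54 ± 0.17). The ratio of POU5F1 itself was 1.65-fold higher (0.72 ± 0.22, adjusted p = 0.0383), but the difference was 0.05 ± 0.14 GC corrected (adjusted p = 0.843). The call was also lost without control replicate 1 at 20% oxygen (adjusted p = 0.156), without siOCT4 replicate 1 (0.127) or 2 (0.136) at 20% oxygen, and without siOCT4 replicate 1 (0.0569) or 2 (0.0576) at 1% oxygen. The POU5F1 value is a ratio and not an RNA level, so it does not show how far the siRNA lowered the mRNA.

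Of the 30 integrated stress response and ATF4 targets, 20 rose and 5 fell (21 and 5 adjusted over the list alone; camera adjusted p = 0.000183). With an estimated correlation the adjusted p of this list was 0.539. TRIB3, a pseudokinase induced by ATF4, rose 9.72-fold (4.81 corrected), DDIT4, an inhibitor of mTORC1 signalling, rose 8.84-fold (5.48 corrected), and ATF3, a stress-induced transcription factor, rose 5.38-fold. DUSP8, a phosphatase of stress-activated kinases, rose 13.8-fold (6.38 corrected), and BHLHE40, a transcriptional repressor induced by hypoxia, rose 5.94-fold. HSPA1A and HSPA1B, near-identical genes for an inducible HSP70 chaperone between which reads could be split, rose 4.78-fold (2.76 corrected) and 4.24-fold (2.56 corrected). NEAT1, a nuclear RNA that codes for no protein, rose 3.65-fold (1.87 ± 0.27) with these mRNAs, and 2.93 ± 0.32 GC corrected.

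Among the 21 glycolysis mRNAs, 17 rose and 0 fell, with the same counts adjusted over the list alone (camera adjusted p = 2.86e-06, and adjusted p = 0.539 with an estimated correlation). ALDOC, an aldolase, rose 3.04-fold (2.01 corrected) and SLC2A1, the glucose transporter GLUT1, rose 2.45-fold. Of the 37 matrix mRNAs, 18 rose and 8 fell (20 and 9 adjusted over the list alone; camera adjusted p = 0.0245, and adjusted p = 0.539 with an estimated correlation). COL1A1 and COL6A3, chains of collagens I and VI, rose 2.60-fold (1.41 corrected) and 2.37-fold, while PLOD2, a lysyl hydroxylase that modifies collagen, fell 5.13-fold (1.48 corrected). Among 16 trophectoderm and trophoblast markers, 5 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.0160, and adjusted p = 0.539 with an estimated correlation). HLA-G, the HLA class I molecule of trophoblast, rose 4.98-fold (3.20 corrected); the list's camera adjusted p was 0.0747 without control replicate 2 at 20% oxygen and 0.467 GC corrected. TAGLN, an actin-binding protein of smooth muscle and fibroblasts, rose 2.39-fold.

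The other 25 lists had camera adjusted p from 0.0697 to 0.969 (HIF-responsive genes 0.126, and 0.0472 without control replicate 1 at 20% oxygen): core and naive pluripotency, amnion, primitive streak, endoderm, mesoderm, neuroectoderm, neural crest, fibroblast, HIF-responsive genes, the nuclear-encoded respiratory chain, mitochondrial and cytosolic ribosomal proteins, translation factors, ER chaperones, heat shock proteins, p53 targets, cell cycle, cholesterol synthesis, interferon response, TGF-beta and WNT targets, proteasome, tRNA synthetases, histones and non-coding RNAs. Of the 39 core and primed pluripotency mRNAs, 4 rose and 14 fell (3 and 13 adjusted over the list alone); the list's median was 0.06, its mean -0.07, camera's direction up and fry's down. USP44, a deubiquitinase, fell 6.31-fold (1.85 corrected), and CD24, a surface glycoprotein with related pseudogenes, fell 4.10-fold. Single members of lists that did not pass also fell: MRPL1 of the mitochondrial ribosome (6.06-fold, 1.87 corrected), PSMA4 of the proteasome (5.67-fold, 2.21 corrected), EIF4E, the cap-binding protein (4.54-fold, 1.98 corrected), CCNA2, cyclin A (4.05-fold, 1.58 corrected), NARS, the asparaginyl-tRNA synthetase (3.87-fold, 1.90 corrected), RPL7 (3.88-fold, 1.68 corrected) and RPS24 (2.86-fold) of the cytosolic ribosome, and TUG1, a long non-coding RNA (3.99-fold, 1.72 corrected).

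At 20% oxygen 8450 of 15864 genes passed limma's test, 3041 higher and 5409 lower in siOCT4 cells; 5389 did without siOCT4 replicate 1 at 20% oxygen (964 higher, 4425 lower), 5063 without replicate 2 (836 higher, 4227 lower) and 6335 without control replicate 1 (1590 higher, 4745 lower). GC corrected, 2375 genes passed (1151 higher, 1224 lower), and 1555 of 8313 calls with a GC value kept their direction and 215 were called the opposite way. The GC corrected count was 4 and 3 without siOCT4 replicate 1 and 2 at 20% oxygen (3484 and 3455 at an unadjusted p under 0.05), 746 without control replicate 1 at 20% oxygen, 1560 and 1567 without the control cultures at 1% and 1219 and 1207 without the siOCT4 cultures at 1%. Of the 30 genes described, 29 passed GC corrected, all but POU5F1, and 1, GDF15 (4.78 ± 0.14, adjusted p = 0.00102), passed whichever culture was left out; the corrected call of CDK1 was lost in 6 of these 8 fits. GC corrected, 19 of 30 stress response targets rose and 1 fell (21 and 1 adjusted over the list alone; camera adjusted p = 9.61e-10, and adjusted p = 0.423 with an estimated correlation), and 21 of 59 HIF-responsive mRNAs rose and 3 fell (22 and 6 adjusted over the list alone; camera adjusted p = 0.000399, and adjusted p = 0.423 with an estimated correlation).

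At 1% oxygen, siOCT4 cells had lower ratios than control siRNA cells for mRNAs of the ribosome and higher ratios for mRNAs of pluripotency genes, although 0 lists passed with an estimated correlation (lowest adjusted p = 0.184, and 0.147 GC corrected). RPL8, a protein of the large ribosomal subunit, fell 5.84-fold (3.21 corrected; -2.55 ± 0.40, adjusted p = 0.00268), and RPS9, a protein of the small subunit, fell 5.00-fold (3.25 corrected; -2.32 ± 0.23, adjusted p = 0.000542). L1TD1, an RNA-binding protein of human pluripotent cells, rose by 3.81 ± 0.15 on the log2 scale (2.18 corrected; adjusted p = 0.000303), and APELA, a peptide hormone made by embryonic stem cells, rose 57.2-fold (16.7 corrected; 5.84 ± 0.25, adjusted p = 0.000303). POU5F1 fell 1.95-fold (-0.96 ± 0.22, adjusted p = 0.0116) and -0.47 ± 0.14 GC corrected (adjusted p = 0.0408); the call was lost without control replicate 1 at 1% oxygen (adjusted p = 0.0538) or without siOCT4 replicate 1 at 1% oxygen (0.0619), and the corrected call in 6 of the 8 fits with a culture left out (highest adjusted p = 0.191).

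Of the 79 cytosolic ribosomal protein mRNAs, 66 fell and 0 rose (68 and 0 adjusted over the list alone; camera adjusted p = 1.82e-21, and adjusted p = 0.256 with an estimated correlation). Their median change was -1.42, and GC corrected 76 fell and 0 rose (77 and 0 adjusted over the list alone; camera adjusted p = 2.92e-22, and adjusted p = 0.225 with an estimated correlation). Pseudogene copies could take part of the reads of these genes. RPL36 fell 5.95-fold (3.05 corrected). Of 65 nuclear-encoded respiratory chain mRNAs, 39 fell and 5 rose (41 and 6 adjusted over the list alone; camera adjusted p = 3.72e-09, and adjusted p = 0.300 with an estimated correlation). NDUFA13, a subunit of complex I, fell 4.62-fold (2.68 corrected) and COX5B, a subunit of cytochrome c oxidase, fell 3.98-fold. Of 76 mitochondrial ribosomal protein mRNAs, 28 fell and 19 rose (29 and 19 adjusted over the list alone; camera adjusted p = 0.00647, and adjusted p = 0.531 with an estimated correlation). GC corrected, 41 of them fell and 2 rose (45 and 2 adjusted over the list alone; camera adjusted p = 8.62e-08, and adjusted p = 0.267 with an estimated correlation). MRPL28 fell by 2.00 on the log2 scale (1.33 corrected). The GC corrected counts do not take account of transcript length, which correlated with the ratio in siOCT4 cells at 1% oxygen (Spearman 0.381 and 0.373).

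Among the 39 core and primed pluripotency mRNAs, 24 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.00430, and adjusted p = 0.184 with an estimated correlation). USP44 rose 13.5-fold (4.04 corrected) and TERF1, a telomere-binding protein abundant in pluripotent cells, rose 10.2-fold (3.504 corrected). GC corrected, 24 rose and 3 fell (24 and 4 adjusted over the list alone; camera adjusted p = 6.59e-06, and adjusted p = 0.147 with an estimated correlation). FGF8, a growth factor of the primitive streak, rose 5.42-fold (11.2 corrected) and SIX3, a transcription factor of the anterior neural plate, rose 34.5-fold, although their lists did not pass camera. HAS2, a hyaluronan synthase, rose 35.4-fold (10.4 corrected). ID1 and ID2, targets of BMP signalling that inhibit bHLH factors, rose 4.08-fold and 6.53-fold, and GC corrected 13 of 24 TGF-beta, activin, BMP and WNT targets rose and 3 fell (14 and 3 adjusted over the list alone; camera adjusted p = 0.00210, and adjusted p = 0.190 with an estimated correlation).

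Glycolysis, HIF and stress mRNAs were lower in siOCT4 cells at 1% oxygen. Of 21 glycolysis mRNAs, 17 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 4.66e-09, and adjusted p = 0.256 with an estimated correlation). PGK1 and ALDOA, glycolytic enzymes whose mRNAs have processed pseudogenes, fell 4.51-fold (11.6 corrected) and 4.02-fold (2.46 corrected), ALDOC fell 5.01-fold, and SLC16A3, the lactate exporter MCT4, fell 15.4-fold (8.68 corrected). Of 59 HIF-responsive mRNAs, 26 fell and 14 rose, also adjusted over the list alone (camera adjusted p = 0.000749, and adjusted p = 0.184 with an estimated correlation); CA9, a carbonic anhydrase induced by HIF, fell 23.1-fold (14.7 corrected). Of 30 stress response targets, 22 fell and 4 rose, also adjusted over the list alone (camera adjusted p = 9.40e-07, and adjusted p = 0.184 with an estimated correlation). DDIT4 fell 7.06-fold, GDF15 6.05-fold (3.36 corrected), SLC3A2, the heavy chain of amino acid transporters, 5.46-fold and TRIB3 5.28-fold (2.90 corrected). NEAT1 fell 4.03-fold (9.81 corrected) and SNHG5, a host transcript of small nucleolar RNAs, 3.74-fold (6.78 corrected) alongside them.

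Of 25 cholesterol synthesis mRNAs, 15 fell and 7 rose (15 and 8 adjusted over the list alone; camera adjusted p = 0.00430, and adjusted p = 0.184 with an estimated correlation). MVD, an enzyme of the mevalonate pathway, fell 6.46-fold (3.17 corrected). Of 37 matrix mRNAs, 18 fell and 9 rose, also adjusted over the list alone (camera adjusted p = 0.00430, and adjusted p = 0.436 with an estimated correlation). COL18A1 and COL4A2, basement membrane collagens, fell 5.56-fold (2.55 corrected) and 3.81-fold (2.21 corrected). Of 16 trophectoderm and trophoblast markers, 8 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.00203, and adjusted p = 0.300 with an estimated correlation); the keratins KRT8 and KRT19 fell 2.90-fold (1.83 corrected) and 2.87-fold (1.68 corrected). Of 11 fibroblast and stroma markers, 5 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.0212, and adjusted p = 0.509 with an estimated correlation), with TAGLN 4.60-fold lower; GC corrected this list had a camera adjusted p of 0.115. Of 16 histone mRNAs, 4 fell and 0 rose (2 and 0 adjusted over the list alone; camera adjusted p = 0.00652, and adjusted p = 0.184 with an estimated correlation). Single cell cycle and translation mRNAs rose: BUB1B, a mitotic checkpoint kinase, 11.7-fold (4.55 corrected), RRM2, a ribonucleotide reductase subunit, 11.5-fold (5.56 corrected), and EIF5B, a factor of subunit joining, 11.6-fold (3.54 corrected). GC corrected, 23 of 31 proteasome mRNAs fell and 2 rose (24 and 2 adjusted over the list alone; camera adjusted p = 1.40e-06, and adjusted p = 0.267 with an estimated correlation), while PSMD6 rose 3.20-fold (1.498 corrected).

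At 1% oxygen 9672 genes passed, 6516 higher and 3156 lower in siOCT4 cells; the lower ones were 1904 without control replicate 1 at 1% oxygen and 2047 without siOCT4 replicate 2 at 1%. The median of all genes changed by 0.42; with each culture shifted to the same median, by -0.38 for this comparison, 5159 genes were higher and 4626 lower. GC corrected, 6813 genes passed (3346 higher, 3467 lower), and 4600 of 9466 calls kept their direction and 546 were called the opposite way. Of the 37 genes described, 37 passed GC corrected and 33 whichever culture was left out.

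Lowering oxygen from 20% to 1% in control siRNA cells went with higher ratios of stress, hypoxia and glycolysis mRNAs and lower ratios of pluripotency mRNAs, although 0 lists passed with an estimated correlation (lowest adjusted p = 0.211, and 0.0513 GC corrected). GDF15 rose 167-fold (93.5 corrected; 7.38 ± 0.31, adjusted p = 0.000152), from a mean ratio of 0.0178 ± 0.00455 (SD) to 2.95 ± 0.582. APELA fell 216-fold (46.2 corrected; -7.75 ± 0.25, adjusted p = 0.000152), from 15.5 ± 3.73 to 0.0711 ± 0.00643. Whether libraries were exchanged between the control groups is open, as described under the flagged results, so these changes need not be effects of oxygen. DDIT3 rose 17.5-fold (4.13 ± 0.15), L1TD1 fell 12.5-fold (3.53 corrected; -3.65 ± 0.15) and PGK1 rose 5.30-fold (13.7 corrected; 2.41 ± 0.15). The POU5F1 ratio was 0.869 ± 0.158 (SD) at 20% and 0.972 ± 0.229 at 1% oxygen, a difference of 0.15 ± 0.22 (adjusted p = 0.580), and of -0.39 ± 0.14 GC corrected (adjusted p = 0.0719).

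Of the 30 integrated stress response and ATF4 targets, 24 rose and 2 fell (24 and 3 adjusted over the list alone; camera adjusted p = 3.31e-09, and adjusted p = 0.211 with an estimated correlation). GC corrected, 27 rose and 1 fell (28 and 1 adjusted over the list alone; camera adjusted p = 3.11e-12, and adjusted p = 0.126 with an estimated correlation). DDIT4 rose 35.1-fold, TRIB3 24.5-fold (13.6 corrected) and SESN2, a sestrin that restrains mTORC1, 7.24-fold (4.65 corrected). JUN, an AP-1 transcription factor, rose 32.1-fold and DUSP8 34.9-fold (18.2 corrected). Among 14 cytosolic heat shock mRNAs, whose list did not pass (camera adjusted p = 0.402), HSPA1B rose 16.3-fold (10.8 corrected), HSPA1A 14.8-fold (9.46 corrected) and BAG3, an HSP70 co-chaperone, 8.45-fold. SARS and AARS, the seryl- and alanyl-tRNA synthetases, rose 3.72-fold and 3.65-fold; GC corrected 14 of 20 synthetase mRNAs rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.00307, and adjusted p = 0.459 with an estimated correlation). NEAT1 rose 11.1-fold with the stress mRNAs (4.72 ± 0.32 GC corrected), while TUG1 fell 6.59-fold (2.47 corrected).

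Of 59 HIF-responsive mRNAs, 28 rose and 12 fell (29 and 13 adjusted over the list alone; camera adjusted p = 0.000226, and adjusted p = 0.211 with an estimated correlation). BHLHE40 rose 20.1-fold, NDRG1, a stress-responsive protein, 8.38-fold and CA9 18.2-fold (11.4 corrected); the CA9 call was lost without control replicate 1 at 1% oxygen (adjusted p = 0.0614) or at 20% oxygen (0.0628). Of 21 glycolysis mRNAs, 20 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 1.71e-09, and adjusted p = 0.236 with an estimated correlation). SLC16A3 rose 24.4-fold (13.8 corrected) and ALDOC 7.05-fold. GC corrected, 36 HIF-responsive mRNAs rose and 4 fell (37 and 5 adjusted over the list alone; camera adjusted p = 3.84e-07, and adjusted p = 0.189 with an estimated correlation).

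Of 39 core and primed pluripotency mRNAs, 26 fell and 1 rose (27 and 1 adjusted over the list alone; camera adjusted p = 0.00270, and adjusted p = 0.211 with an estimated correlation). USP44 fell 24.3-fold (5.68 corrected), CD24 18.9-fold and TERF1 17.6-fold (5.53 corrected). GC corrected, 26 fell and 2 rose (27 and 2 adjusted over the list alone; camera adjusted p = 9.37e-07, and adjusted p = 0.0513 with an estimated correlation). FGF8 fell 9.45-fold (18.99 corrected), SIX3 26.1-fold, ID2 11.9-fold and HAS2 48.3-fold (10.6 corrected). GC corrected, 14 of 24 TGF-beta, activin, BMP and WNT targets fell and 4 rose (15 and 4 adjusted over the list alone; camera adjusted p = 0.00398, and adjusted p = 0.162 with an estimated correlation). GMNN, an inhibitor of replication licensing, fell 12.3-fold (4.88 corrected) and RRM2 10.9-fold (5.82 corrected), although the cell cycle list did not pass (camera adjusted p = 0.805).

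Of 37 matrix mRNAs, 23 rose and 3 fell (25 and 3 adjusted over the list alone; camera adjusted p = 1.02e-06, and adjusted p = 0.236 with an estimated correlation). COL18A1 rose 6.78-fold (3.20 corrected), HSPG2, the basement membrane proteoglycan perlecan, 6.11-fold (3.21 corrected) and COL1A1 3.46-fold (2.09 corrected). Of 25 mRNAs of cholesterol biosynthesis, 15 rose and 7 fell (15 and 8 adjusted over the list alone; camera adjusted p = 0.0308, and adjusted p = 0.236 with an estimated correlation). MVD rose 8.53-fold (4.29 corrected); the list's adjusted p was 0.0907 without control replicate 2 at 20% oxygen. Of 16 trophectoderm and trophoblast markers, 10 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.00270, and adjusted p = 0.308 with an estimated correlation), with KRT8 2.91-fold (1.82 corrected) higher. Of 11 fibroblast and stroma markers, 7 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.0311, and adjusted p = 0.464 with an estimated correlation), with TAGLN 4.57-fold higher. Of 16 mRNAs of replication-dependent histones, 5 rose and 0 fell (3 and 0 adjusted over the list alone; camera adjusted p = 0.0428, and adjusted p = 0.236 with an estimated correlation). GC corrected, the camera adjusted p of the last 3 lists was 0.0778, 0.136 and 0.196; without control replicate 1 at 20% oxygen that of the histones was 0.118, and without siOCT4 replicate 1 or 2 at 1% oxygen 0.0546 or 0.0548.

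In control cells 9545 genes passed, 3255 higher and 6290 lower at 1% oxygen; the higher ones were 2015 without control replicate 1 at 1% oxygen. The median of all genes changed by -0.31, and shifting each culture to the same median raised it by 0.20. GC corrected, 7078 genes passed (3541 higher, 3537 lower), and 4752 of 9337 calls kept their direction and 668 were called the opposite way. Of the 38 genes described, 37 passed GC corrected, all but POU5F1, and 36 whichever culture was left out.

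In siOCT4 cells, 1% oxygen went with lower ratios of ribosomal and respiratory chain mRNAs than 20% oxygen, although 0 lists passed with an estimated correlation (lowest adjusted p = 0.595, and 0.390 GC corrected). RPS21 of the small ribosomal subunit fell 5.00-fold (-2.32 ± 0.23, adjusted p = 0.000789), from a mean ratio of 0.858 ± 0.0383 (SD) to 0.172 ± 0.0162, and RPL35 of the large subunit fell 4.73-fold (2.999 corrected; -2.24 ± 0.21, adjusted p = 0.000754). NDUFA13 fell 4.49-fold (2.33 corrected; -2.17 ± 0.46, adjusted p = 0.00933). HSPH1 and HSP90AA1, inducible cytosolic chaperones, rose 5.96-fold (2.34 corrected; 2.58 ± 0.17) and 4.55-fold (2.31 corrected; 2.19 ± 0.15). POU5F1 fell 2.89-fold (-1.53 ± 0.22, adjusted p = 0.00231), and -0.91 ± 0.14 GC corrected (adjusted p = 0.00673).

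Of 79 cytosolic ribosomal protein mRNAs, 67 fell and 0 rose (69 and 0 adjusted over the list alone; camera adjusted p = 3.06e-19, and adjusted p = 0.595 with an estimated correlation). RPL36 and RPL8 fell 4.93-fold (2.23 corrected) and 4.69-fold (2.30 corrected), and the median change of the list was -1.34. Of 65 nuclear-encoded respiratory chain mRNAs, 47 fell and 2 rose (49 and 2 adjusted over the list alone; camera adjusted p = 9.24e-13, and adjusted p = 0.595 with an estimated correlation), with NDUFS7 of complex I at -2.07 on the log2 scale (-0.72 corrected). Of 76 mitochondrial ribosomal protein mRNAs, 41 fell and 9 rose (43 and 10 adjusted over the list alone; camera adjusted p = 1.47e-06, and adjusted p = 0.595 with an estimated correlation). MRPL12 and MRPS34 fell 4.23-fold (1.92 corrected) and 4.16-fold (1.89 corrected). Of 21 glycolysis mRNAs, 14 fell and 2 rose, also adjusted over the list alone (camera adjusted p = 8.03e-05, and adjusted p = 0.595 with an estimated correlation). GAPDH and TPI1, glycolytic enzymes with many pseudogenes in the case of GAPDH, fell 2.62-fold (1.61 corrected) and 2.58-fold, PFKL, a phosphofructokinase, fell 2.83-fold (1.36 corrected) and ALDOA 2.47-fold (1.36 corrected).

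GC corrected, 73 ribosomal protein mRNAs, 56 respiratory chain mRNAs and 59 mitochondrial ribosomal protein mRNAs fell and 0 rose (78, 59 and 63 fell adjusted over the list alone; camera adjusted p = 3.95e-25, 3.47e-20 and 8.30e-17). With an estimated correlation the adjusted p of these 3 lists was 0.390. The GC correction does not model transcript length. Across mRNAs, length correlated with the ratio at 0.381 and 0.373 at 1% and -0.157 and -0.259 at 20% oxygen (Spearman). Ribosomal protein and respiratory chain mRNAs were short (median 910 and 942 nucleotides), so length may add to these falls. Corrected for both, their median changes against siOCT4 cells at 20% and control cells at 1% oxygen together were -1.08 and -0.748. Of 31 proteasome mRNAs, 19 fell and 1 rose GC corrected (21 and 1 adjusted over the list alone; camera adjusted p = 1.49e-07, and adjusted p = 0.537 with an estimated correlation). PSMA7 and PSMB5, subunits of the catalytic core, fell 2.58-fold and 2.54-fold. Of 14 cytosolic heat shock mRNAs, 9 rose and 1 fell GC corrected, also adjusted over the list alone (camera adjusted p = 0.00119, and adjusted p = 0.390 with an estimated correlation).

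Genes of lists that did not pass also changed. Trophectoderm and trophoblast markers were closest to passing (camera adjusted p = 0.0627, and 0.0233 without siOCT4 replicate 2 at 1% oxygen or 0.0477 without siOCT4 replicate 2 at 20% oxygen). COL12A1, a fibril-associated collagen, rose 6.17-fold (3.40 corrected) and FN1, fibronectin, 3.29-fold, while THY1, a surface glycoprotein of fibroblasts and stem cells, fell 2.88-fold. BUB1B rose 6.17-fold (2.75 corrected), TOP2A, the topoisomerase of dividing cells, 5.35-fold (2.03 corrected) and EIF3A, a subunit of initiation factor 3, 5.50-fold (2.41 corrected). L1TD1 rose 3.64-fold (1.42 corrected), while LEFTY2, an inhibitor of NODAL, fell 2.90-fold (1.72 corrected) and GAL, the neuropeptide galanin made by embryonic stem cells, fell 3.15-fold (1.72 corrected). KDM3A, a HIF-induced histone demethylase, rose 4.58-fold (2.46 corrected), SNHG5 fell by 1.81 on the log2 scale (2.57 corrected) and POMC, the precursor of ACTH, fell 28.3-fold (11.5 corrected). All 20 genes ranked by size of change in this comparison had a recurrent ratio, which comes from small read numbers.

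In siOCT4 cells 9362 genes passed, 5936 higher and 3426 lower at 1% oxygen; the lower ones were 2149 and 2084 without siOCT4 replicate 1 and 2 at 1% oxygen and 1993 and 1717 without replicate 1 and 2 at 20%. The median of all genes changed by 0.27; with each culture shifted to the same median, by -0.26 for this comparison, 4982 genes were higher and 4615 lower. GC corrected, 5668 genes passed (2901 higher, 2767 lower), 3903 of 9177 calls kept their direction and 250 were called the opposite way; 3002 and 3556 passed without siOCT4 replicate 1 and 2 at 1% oxygen and 2888 and 2135 without replicate 1 and 2 at 20%. Of the 29 genes described, 29 passed GC corrected and 18 whichever culture was left out.

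**Figure D2:**
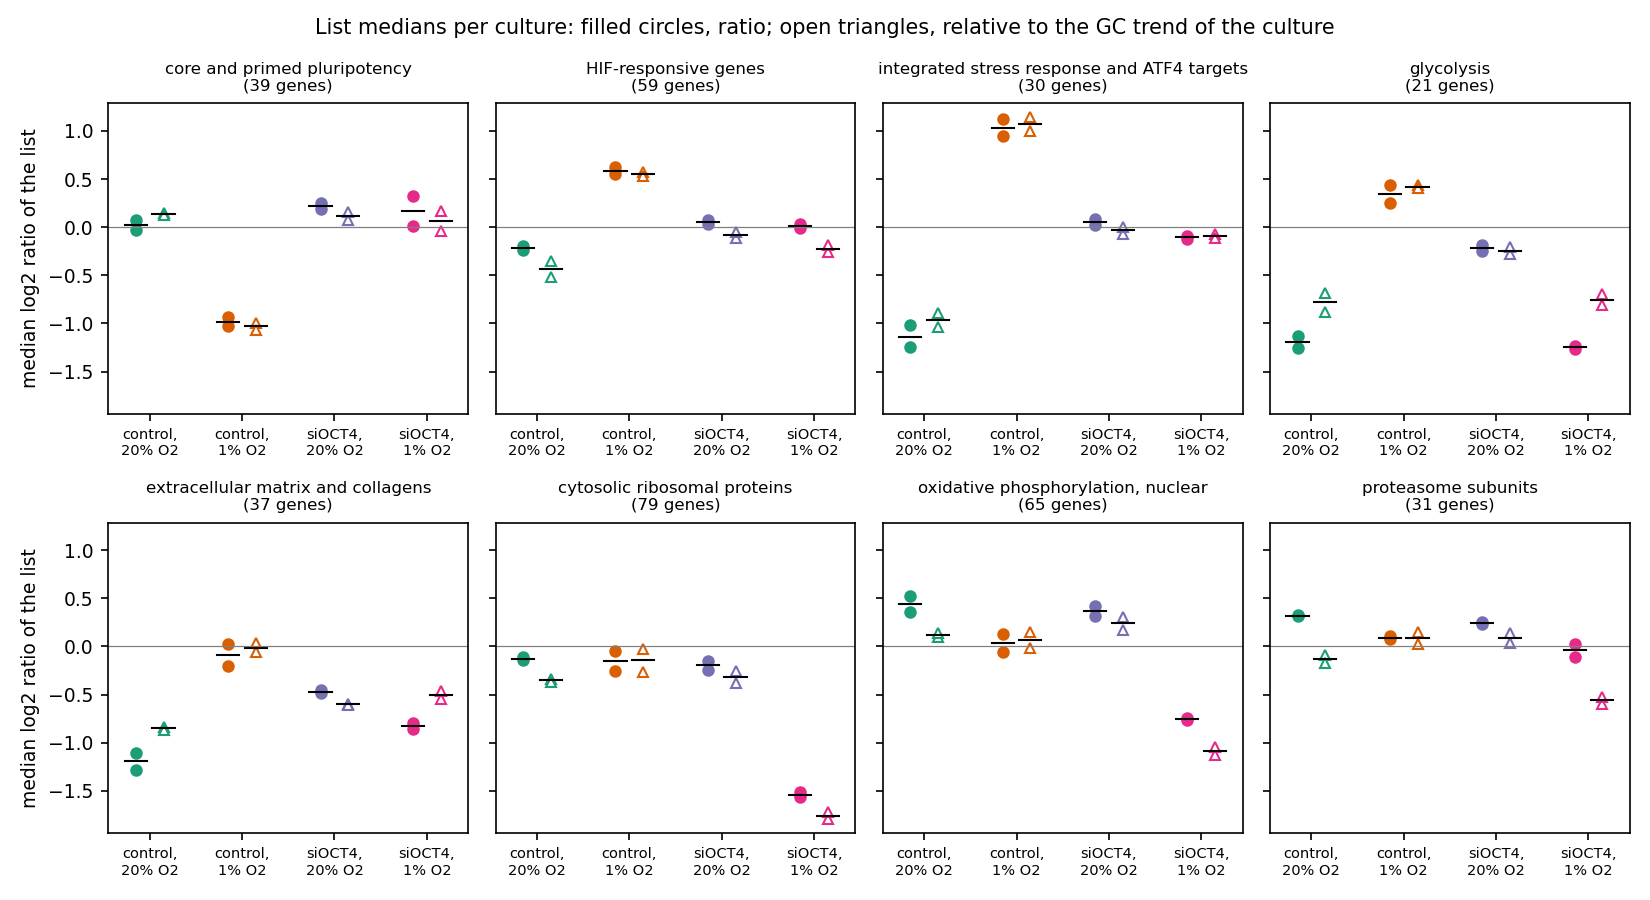
Median log2 translation ratio of 8 gene lists in each culture (filled circles) and relative to the culture's GC trend (open triangles), with group means as lines. The ribosomal protein median was -1.56 and -1.51 in the siOCT4 cultures at 1% oxygen and between -0.26 and -0.05 in the other 6, and the pluripotency median was -1.03 and -0.94 in control cells at 1% oxygen.

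The change with siOCT4 differed between 1% and 20% oxygen for mRNAs of stress and glycolysis genes, and for single pluripotency mRNAs, although 0 lists passed with an estimated correlation (lowest adjusted p = 0.421, and 0.188 GC corrected). The siOCT4 effect on APELA was higher at 1% than at 20% oxygen by 8.99 ± 0.35 on the log2 scale (5.37 corrected; adjusted p = 8.04e-05) and that on L1TD1 by 5.51 ± 0.21 (2.32 corrected). For GDF15 the difference was -8.38 ± 0.44 (-6.53 corrected) and for DDIT4 -5.96 ± 0.61 (-4.76 corrected). For PGK1 it was -3.25 ± 0.21 (-5.79 corrected), for RPL8 -4.11 ± 0.57 (-2.23 corrected) and for RPS9 -3.36 ± 0.32 (-1.95 corrected). For POU5F1 it was -1.68 ± 0.32 (adjusted p = 0.00420), and -0.52 ± 0.20 GC corrected (adjusted p = 0.0845).

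Of 21 glycolysis mRNAs, 18 had a negative and 0 a positive difference, also adjusted over the list alone (camera adjusted p = 6.62e-08, and adjusted p = 0.421 with an estimated correlation), with ALDOC at -3.93 (-2.93 corrected) and SLC16A3 at -6.62 (-4.80 corrected). Among 30 stress response targets 22 were negative and 5 positive, also adjusted over the list alone (camera adjusted p = 1.24e-05, and adjusted p = 0.421 with an estimated correlation), with TRIB3 at -5.68 (-3.80 corrected). Of 79 cytosolic ribosomal protein mRNAs, 51 were negative and 6 positive, also adjusted over the list alone (camera adjusted p = 4.56e-08, and adjusted p = 0.458 with an estimated correlation). Of 65 respiratory chain mRNAs, 26 were negative and 12 positive (26 and 10 adjusted over the list alone; camera adjusted p = 0.00785, and adjusted p = 0.659 with an estimated correlation), with NDUFA13 at -3.38 (-1.66 corrected). Of 59 HIF-responsive mRNAs, 28 were negative and 17 positive (29 and 18 adjusted over the list alone; camera adjusted p = 0.00785, and adjusted p = 0.421 with an estimated correlation). Of 37 matrix mRNAs, 23 were negative and 9 positive (23 and 10 adjusted over the list alone; camera adjusted p = 0.00785, and adjusted p = 0.458 with an estimated correlation), with COL18A1 at -4.13 (-1.71 corrected).

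Trophectoderm and trophoblast markers were negative for 9 and positive for 1 of 16 (8 and 1 adjusted over the list alone; camera adjusted p = 0.00352, and adjusted p = 0.458 with an estimated correlation). Fibroblast and stroma markers were negative for 8 and positive for 1 of 11, also adjusted over the list alone (camera adjusted p = 0.0188, and adjusted p = 0.458 with an estimated correlation). The replication-dependent histones were negative for 5 and positive for 0 of 16 (4 and 0 adjusted over the list alone; camera adjusted p = 0.0251, and adjusted p = 0.421 with an estimated correlation), with an adjusted p of 0.104 without control replicate 1 at 20% oxygen. GC corrected, the fibroblast and stroma list and the histones did not pass (camera adjusted p = 0.0591 and 0.0633). The pluripotency list did not pass in the ratios as deposited (camera adjusted p = 0.143). GC corrected, 22 of 39 pluripotency mRNAs were positive and 4 negative (24 and 4 adjusted over the list alone; camera adjusted p = 0.000599, and adjusted p = 0.188 with an estimated correlation); CD24 was at 5.03, TERF1 at 5.02 (2.04 corrected) and USP44 at 6.41 (2.90 corrected). HAS2 was at 7.71 (4.11 corrected), SIX3 at 4.57, ID2 at 3.81 and MVD at -4.67 (-2.46 corrected).

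The interaction passed for 10893 genes, 6736 positive and 4157 negative, with a median over all genes of 0.49 that centring lowered by 0.46 (log2). GC corrected, 6713 genes passed (3420 positive, 3293 negative), and 4384 of 10663 calls kept their sign and 865 were called with the opposite one.

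**Figure D3:**
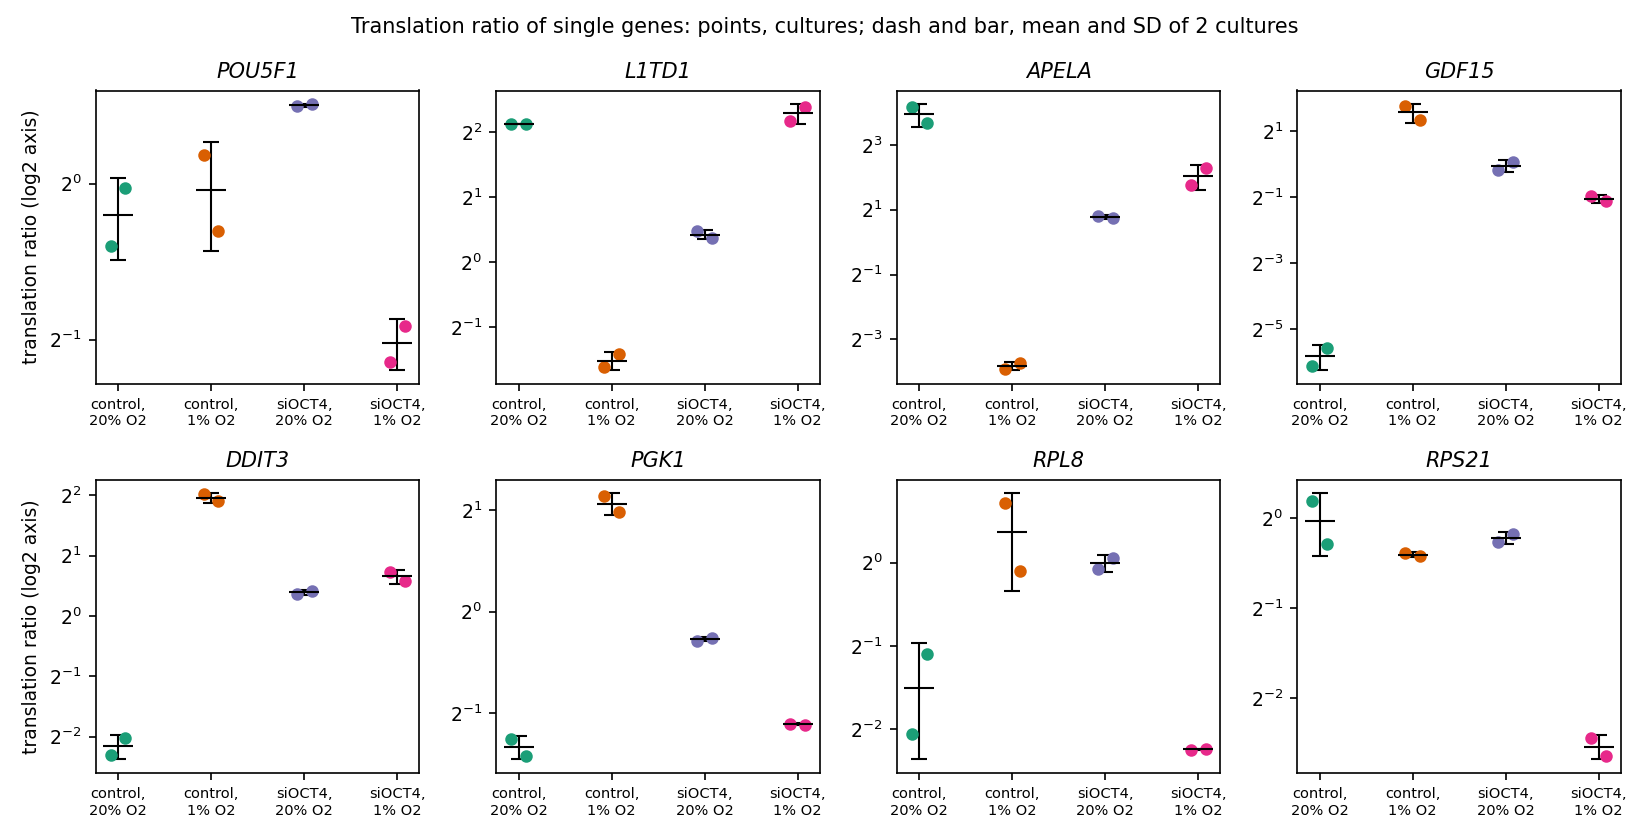
Translation ratio (log2 axis) of 8 genes in each culture (points), with the mean and SD of the 2 cultures of a group. GDF15 had a mean ratio of 0.0178 in control cells at 20% oxygen and 2.95 at 1%, and RPL8 one of 0.212 in siOCT4 cells at 1% oxygen.

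**Figure D4:**
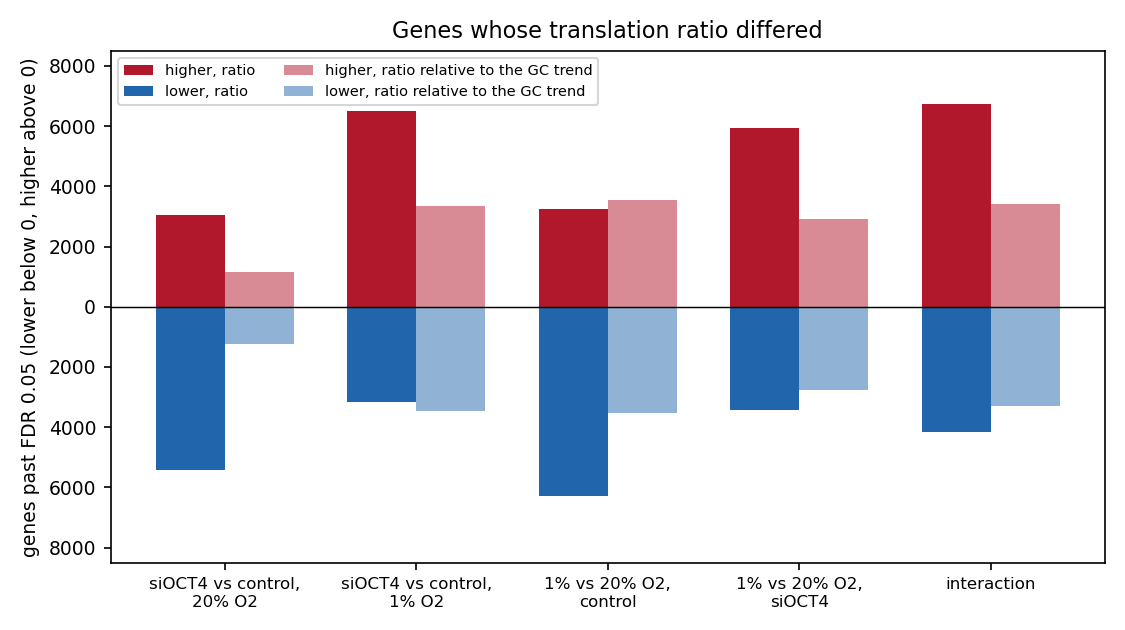
Number of genes past an FDR of 0.05 in each comparison, higher above 0 and lower below 0, for the ratio as deposited (dark bars) and relative to the GC trend (pale bars). The comparison of siOCT4 with control cells at 20% oxygen went from 8450 to 2375 genes.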

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

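Of the tests below, the one of the GC trend by non-coding RNAs was planned before its result was seen; the tests on ribosomal protein mRNAs and on stress, HIF and pluripotency mRNAs were chosen only after the results were seen.

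In the ratios as deposited, limma's interaction term passed for 10893 genes. In simulated data a GC trend alone gave 11183 such calls among unchanged genes, so this count does not measure how many siOCT4 effects differed. GC corrected, 6713 genes passed, and of 10663 calls 4384 kept their sign and 865 were called with the opposite one. By camera the interaction differed for 9 lists, with median log2 values of -2.52 for glycolysis, -2.29 for stress response targets, -1.99 for trophectoderm and trophoblast, -1.40 for cytosolic ribosomal proteins, -1.25 for histones, -1.04 for fibroblast and stroma, -1.04 for the extracellular matrix, -0.59 for HIF-responsive genes and -0.38 for the nuclear-encoded respiratory chain. These medians are of the ratios as deposited. GC corrected, 7 of the 9 lists passed in the same direction, and the fibroblast and stroma list and the histones did not. With an estimated correlation 0 of the 9 lists passed, the lowest adjusted p being 0.421. The 88 genes described singly were chosen after their values were seen, so the counts that follow do not measure how many calls hold. Of the 88 genes, 86 passed the interaction, 32 with positive and 54 with negative values. GC corrected, 73 of the 86 passed with the same sign; RPL7 passed with the opposite one, and POU5F1, PLOD2, CDK1, MRPL1, RPS24, CA9, MRPL12, MRPS34, HSPH1, COL12A1, GAL and THY1 did not pass. For single genes, where the correction changed a value by more than 1.5 times as a fold, the corrected value follows it, marked "corrected".

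Among stress response, heat shock and p53-linked genes, the interaction log2 values were GDF15 -8.38 (-6.53 corrected), DUSP8 -5.81 (-3.73 corrected), TRIB3 -5.68 (-3.80 corrected), DDIT4 -5.96 (-4.76 corrected), DDIT3 -3.86 (-4.47 corrected), ATF3 -3.82, SLC3A2 -4.08 (-2.98 corrected), SESN2 -3.30 (-1.90 corrected), JUN -4.36 (-3.37 corrected), HSPA1A -3.14 (-1.71 corrected), HSPA1B -3.17 (-1.88 corrected), BAG3 -2.53 (-1.50 corrected), HSPH1 3.41 (0.26 corrected) and HSP90AA1 3.36 (1.37 corrected). Among HIF-responsive and glycolysis genes, the interaction log2 values were BHLHE40 -3.33, CA9 -5.19 (-3.72 corrected), NDRG1 -3.75 (-2.56 corrected), KDM3A 4.11 (2.34 corrected), SLC16A3 -6.62 (-4.80 corrected), SLC2A1 -2.78 (-2.12 corrected), ALDOC -3.93 (-2.93 corrected), ALDOA -3.19 (-1.62 corrected), PGK1 -3.25 (-5.79 corrected), GAPDH -2.50 (-1.19 corrected), TPI1 -2.52 (-1.43 corrected) and PFKL -2.92 (-0.998 corrected). Among pluripotency, germ layer and signalling genes, the interaction log2 values were POU5F1 -1.68 (-0.52 corrected), L1TD1 5.51 (2.32 corrected), APELA 8.99 (5.37 corrected), USP44 6.41 (2.90 corrected), LIN28B 4.63 (1.92 corrected), CD24 5.03, TERF1 5.02 (2.04 corrected), GAL -1.49 (0.10 corrected), FGF8 1.91 (4.15 corrected), SIX3 4.57, ID1 1.39 (2.52 corrected) and ID2 3.81. Among ribosomal, respiratory chain, proteasome and other translation genes, the interaction log2 values were RPL7 1.44 (-1.15 corrected), RPS24 0.91, RPL36 -3.26 (-1.18 corrected), RPL8 -4.11 (-2.23 corrected), RPS9 -3.36 (-1.95 corrected), RPS21 -1.97, RPL35 -2.33 (-1.11 corrected), NDUFA13 -3.38 (-1.66 corrected), COX5B -2.37, NDUFS7 -3.36 (-0.91 corrected), MRPL1 3.37 (-0.03 corrected), MRPL28 -3.18 (-1.68 corrected), MRPL12 -1.86 (0.21 corrected), MRPS34 -2.49 (-0.42 corrected), PSMA4 3.56 (0.71 corrected), PSMD6 3.10 (1.18 corrected), PSMA7 -1.46, PSMB5 -1.61, EIF4E 3.79 (1.21 corrected), EIF5B 4.91 (1.46 corrected), EIF3A 3.65 (1.06 corrected), NARS 4.23 (1.95 corrected), SARS -2.32 and AARS -1.83. Among matrix, stroma and trophoblast genes, the interaction log2 values were PLOD2 3.63 (0.08 corrected), COL1A1 -2.44 (-0.83 corrected), COL6A3 -1.31, COL18A1 -4.13 (-1.71 corrected), COL4A2 -3.21 (-1.48 corrected), COL12A1 2.46 (0.79 corrected), HSPG2 -3.52 (-1.45 corrected), HAS2 7.71 (4.11 corrected), TAGLN -3.46 (-2.53 corrected), THY1 -0.79 (0.31 corrected), HLA-G -3.77 (-2.68 corrected), KRT8 -2.65 (-1.17 corrected) and KRT19 -2.55 (-0.85 corrected). Among cell cycle, sterol, non-coding and remaining genes, the interaction log2 values were CDK1 3.61 (0.02 corrected), CCNA2 3.42 (0.57 corrected), BUB1B 5.41 (2.89 corrected), RRM2 4.13 (2.32 corrected), GMNN 4.11 (1.64 corrected), TOP2A 4.25 (0.87 corrected), MVD -4.67 (-2.46 corrected), TUG1 4.63 (2.02 corrected), NEAT1 -3.88 (-6.22 corrected), SNHG5 -1.78 (-3.19 corrected) and POMC -6.46 (-4.10 corrected).

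The trend of the ratio on GC content in control cells at 20% oxygen and siOCT4 cells at 1% oxygen was also present in RNAs that code for no long protein. In these 4 cultures the slope of lincRNAs and antisense RNAs was 66.2 to 71.5 percent of the mRNA slope. A limit of 25 percent, under which translation that depends on mRNA composition would be favoured, had been set beforehand for this test. A higher limit, from which a GC content bias of the libraries would be favoured, had also been set and was met in each of the 4 cultures. The trend was thus not confined to mRNAs, and a GC content bias of the RNA or RNC libraries is a candidate explanation. The test cannot exclude translation, since it assumed that ribosomes do not bind these RNAs, which no value here shows. Which of the libraries carries the trend is open, since no values of single libraries are in the table. For the same reason, and since batches are not given in the labels, a preparation shared by these 2 groups and an exchange of RNA or RNC libraries between groups, which would change what each ratio compares, are open.

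Ribosomal protein and respiratory chain mRNAs had lower ratios in siOCT4 cells at 1% oxygen than in the 2 groups that differ from it by 1 factor (with an estimated correlation, adjusted p = 0.256 and 0.595 for ribosomal protein mRNAs and adjusted p = 0.300 and 0.595 for respiratory chain mRNAs). The median log2 change of ribosomal protein mRNAs was -1.40, below all 10000 lists matched on GC content, transcript length and coding length (median -0.365, lowest -0.726), and that of respiratory chain mRNAs was -0.887 (lowest matched list -0.756), which argues against these features, short mRNAs included, as the whole cause. Respiratory chain mRNAs changed by 69.1 percent as much as ribosomal protein mRNAs relative to the GC and length trends. This would argue against regulation through the 5 prime terminal oligopyrimidine tract alone if these mRNAs lack the tract, which was assumed and not checked. As a part of the change such regulation cannot be told apart from chance. The 22 mRNAs with the tract that code for no ribosomal protein had a median of 0.268, at percentile 5.08 of matched lists (median 0.640). A response to both treatments together may underlie the pattern and stays open: the interaction passed for both lists (camera adjusted p = 4.56e-08 and 0.00785, and adjusted p = 0.458 and 0.659 with an estimated correlation), which does not show its cause.

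Stress response, HIF and pluripotency mRNAs differed between control cells at 1% and 20% oxygen. The largest camera adjusted p of the 3 lists was 9.37e-07 after the GC correction and 0.00808 without genes at recurrent ratios. At the preset correlation the differences thus did not rest wholly on the fitted GC trend or on genes at recurrent ratios. The success of the correction in these cultures was not tested, and the criterion was set with these results known. Effects of GC content that the correction leaves therefore stay open. With an estimated correlation 0 of the 3 lists passed (lowest adjusted p = 0.211 as deposited, 0.0513 after the correction and 0.173 without these genes). An exchange of the RNA libraries of the 2 control groups would make the deviations of control from siOCT4 cells at 20% and 1% oxygen mirror each other: they were -0.781 and 1.13 for stress response (69.1 percent in size, 50.1 to 86.1 with single cultures), -0.272 and 0.866 for HIF (31.4 percent, 14.1 to 49.9) and -0.0484 and -1.18 for pluripotency mRNAs (4.10 percent, 0.302 to 5.41). An exchange could also make the 2 control groups correlate negatively across genes. GC corrected, Pearson's r was -0.154 to -0.0842 between their cultures and -0.0111 to 0.32 between cultures of other groups. Genes are not independent, and these values were not tested. Since an siOCT4 effect on pluripotency mRNAs would also break the mirror, an exchange cannot be told apart from an effect of oxygen on translation or on RNA levels without values of single libraries.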

How the results depend on the processing

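The GC correction, the GC and length correction, quantile normalization, leaving out genes with a recurrent ratio and their combinations with a culture left out were chosen after seeing the data. For siOCT4 against control cells at 20% oxygen, 8450 genes became 2375 with the GC correction, 2528 with GC and length, 1838 with quantile normalization and 5063 (without siOCT4 replicate 2 at 20% oxygen) to 9244 (without control replicate 2 at 20%) with a culture left out. The GC corrected count was 3 (without siOCT4 replicate 2 at 20%; 3455 at an unadjusted p under 0.05 in limma) to 1933 (without control replicate 2 at 20%). At 1% oxygen, 9672 became 6277 with GC and length, 6405 with quantile normalization and 6422 without recurrent ratios. In control cells, 9545 became 6230 without recurrent ratios. In siOCT4 cells, 9362 became 5668 with the GC correction, 4552 with GC and length and 5018 with quantile normalization, and the GC corrected count was 2135 (without siOCT4 replicate 2 at 20%) to 6207 (without control replicate 2 at 20%). The interaction went from 10893 to 6713, 6512, 7034 and 6874 under the GC correction, GC and length, quantile normalization and without recurrent ratios. Leaving out genes with a recurrent ratio tested 8087 genes, which accounts for lower counts there; for the other settings the cause was not tested. Apart from these ranges, the other totals stayed within 1.5 times the reported one of their kind, as deposited or GC corrected, including those with the replicate block (7354, 9063, 8885, 8613 and 10484) and, against the GC corrected totals, those also without recurrent ratios (2988, 5147, 5114, 4849 and 5079). Counts by direction moved more: with a culture left out, 3041 higher and 5409 lower genes at 20% oxygen became 836 to 3916 and 4227 to 5373, 6516 and 3156 at 1% oxygen 5556 to 6734 and 1904 to 3563, 3255 and 6290 in control cells 2015 to 3745 and 5453 to 6075, 5936 and 3426 in siOCT4 cells 4606 to 6175 and 1717 to 3903, and 6736 and 4157 in the interaction 6239 to 6676 and 3326 to 4526. Fitted with only the groups compared, the higher genes at 20% oxygen and in control cells were 1572 and 2104. Replicate numbers did not pair the cultures: differences between replicates of 2 groups correlated across genes at -0.233 to 0.0225, and genes are not independent.

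With an estimated correlation 0 lists passed camera in each of the 5 comparisons, with and without the GC correction; the lowest adjusted p was 0.539, 0.184, 0.211, 0.595 and 0.421 without it and 0.423, 0.147, 0.0513, 0.390 and 0.188 with it. Of the 4 lists past the threshold at the preset correlation in siOCT4 cells at 1% against 20% oxygen, the count was 9 with the GC correction and 7 with GC and length, and in the interaction 9 became 14 with the GC correction, 7 of them past it in both. GC corrected, 5 lists at 20% oxygen became 3 (without siOCT4 replicate 2 at 20%) to 6 (without control replicate 1 at 20%). Lists outside the random range within control cells at 20% oxygen were 5 as reported, 13 with the GC correction, 14 with GC and length, 10 without replicate 1 and 4 without replicate 2.

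POU5F1 between 1% and 20% oxygen in control cells was 0.15 (adjusted p = 0.580) and reversed to -0.387 with the GC correction (adjusted p = 0.0719, and 0.0338 also without genes at recurrent ratios) and to -0.327 with GC and length; with a culture left out it was -0.0902 to 0.396, and -0.522 to -0.252 GC corrected (-0.385 and -0.389 without control replicate 1 and 2 at 20% oxygen). The cause was not tested. The genes described singly were chosen after their values were seen, so the counts below do not measure how many calls hold. Over all genes, 1555 of 8313, 4600 of 9466, 4752 of 9337, 3903 of 9177 and 4384 of 10663 calls were kept with the GC correction. Of 154 values of genes described singly, 145 of them of genes without a recurrent ratio, 151 kept direction and call with the GC correction and 144 with GC and length. With quantile normalization 134 kept both, 153 with the replicate block and 154 with median centring. With the GC correction and 1 culture left out, 1078 of 1232 did. The comparisons of RNA and of RNC levels, the stricter filter, DESeq2 and edgeR were not run, since the table holds ratios and no counts; removing the filter changes nothing in ratios. Depth is not given, so its limit on these ratios is not known.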

Other observations

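The comparisons of groups that differ in both factors were added after seeing the data, because each pairs groups with a like GC trend. siOCT4 cells at 20% oxygen had higher ratios of pluripotency mRNAs than control cells at 1% oxygen: 21 of 39 were higher and 0 lower (camera adjusted p = 2.86e-11, and adjusted p = 0.0252 with an estimated correlation). HIF-responsive mRNAs were lower for 16 and higher for 1 of 59 (camera adjusted p = 2.50e-10, and adjusted p = 0.0252 with an estimated correlation). Stress response targets were lower for 14 and higher for 0 of 30 (camera adjusted p = 8.06e-15, and adjusted p = 0.0490 with an estimated correlation), and cholesterol synthesis mRNAs lower for 2 and higher for 0 of 25 (camera adjusted p = 9.38e-07, and adjusted p = 0.0425 with an estimated correlation). GC corrected, the adjusted p with an estimated correlation was 0.0256 for pluripotency, 0.114 for HIF-responsive, 0.0896 for stress response and 0.177 for cholesterol synthesis mRNAs. Matrix mRNAs, with 0.143 as deposited, were at 0.0256 GC corrected, with 23 lower and 0 higher of 37, and at 0.104 with GC content and length corrected. In all, 1855 genes passed limma's test, 1393 higher and 462 lower in siOCT4 cells, and 3428 passed GC corrected, 1635 higher and 1793 lower.

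siOCT4 cells at 1% oxygen had lower ratios than control cells at 20% oxygen for 67 of 79 cytosolic ribosomal protein mRNAs and higher ratios for 0 (camera adjusted p = 1.61e-27, and adjusted p = 0.218 with an estimated correlation). Respiratory chain mRNAs were lower for 46 and higher for 1 of 65 (camera adjusted p = 3.64e-18, and adjusted p = 0.218 with an estimated correlation), and mitochondrial ribosomal protein mRNAs lower for 43 and higher for 0 of 76 (camera adjusted p = 5.04e-15, and adjusted p = 0.218 with an estimated correlation). With GC content and length corrected, the medians of these lists, in this order, went from -1.33 to -1.08, from -1.16 to -0.643 and from -0.904 to -0.517. Then 57, 40 and 35 members were lower and 0, 1 and 2 higher. Stress response targets were higher for 15 and lower for 1 of 30 (camera adjusted p = 3.23e-06, and adjusted p = 0.218 with an estimated correlation). In this comparison 4207 genes passed, 2135 higher and 2072 lower, and 5621 passed GC corrected, 2737 higher and 2884 lower.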
